A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

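RNA sequencing data from 6 libraries of the budding yeast Saccharomyces cerevisiae were analysed. The strain was BY4741, a laboratory haploid that lacks HIS3, LEU2, MET17 and URA3. Per the labels' protocols, cells in exponential growth in synthetic complete medium were kept for 1 h without treatment, in medium without nitrogen or in medium without potassium, with 2 libraries per group. Total RNA was purified with on-column DNase treatment, and libraries were made with the KAPA mRNA HyperPrep kit, which selects polyadenylated RNA and keeps the strand of the transcript. The labels name no separate cultures beyond a batch number, so p-values measure the spread between these libraries, not between populations of cultures.

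The authors' deposited files hold estimated counts of reads per annotated feature, which need not be whole, for 7127 features in each library. The columns are those that salmon writes, per the file headers, whereas the submitters' processing notes name STAR 2.7.3a, DESeq2 and genome build R64; the quantifier's version and its strand setting are not given in the sources used here. The authors' deposited TPM values are length-normalised. A deposited table of the whole series holds a signal made by dividing counts by 1 size factor per library, named as DESeq2-normalised counts. Multiplying that table back gave whole reads in 100% of values, and 100% of these equalled the rounded estimated counts, within a tolerance of 0.001 reads. Totals ran from 357839 to 425919 reads per library, a shallow depth at which 1346, 1199, 2372, 2449, 1559 and 1133 features held 10 or more reads in the 2 control, 2 nitrogen and 2 potassium libraries, in that order.

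The features were placed on the R64 reference. Coordinates of 6169 features came from the annotation, and 647 more were placed by a search for an open reading frame of the deposited length on the strand named by the identifier. The same search on 5667 annotated genes without introns placed 5579 once, each at its annotated start, and 88 more than once. Of the mRNA features 99.9% had deposited lengths that are multiples of 3.

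The most abundant features lay opposite well-known genes, and most of them are open reading frames missing from the reference annotation. A feature was therefore paired with a gene when at least 50% of its length, and at least 100 bases, lay opposite exactly 1 annotated gene and that gene was protein-coding. This gave 408 paired features opposite 394 genes, of which 370 features are missing from the reference annotation. The pairing, its limit to protein-coding genes, the rule for naming paired genes and the scaling over paired features were chosen after the data had been seen; the other designs, lists and naming rules were fixed before the data were examined. Most genes have no paired feature.

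Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood test after TMM scaling and filterByExpr, which kept 2325 features, 365 of them paired. All 6 libraries entered 1 fit, with 3 residual degrees of freedom. Benjamini-Hochberg adjustment covered the 2325 features of each comparison, and features with an adjusted p below 0.05 were called. In nitrogen starvation the 2 scalings differ: scaling over the paired features alone raised the median log2 fold change of all features by 1.30 for nitrogen against control, by 0.22 for potassium against control and by 1.08 for nitrogen against potassium. Fold changes and CPM in the text use TMM unless stated, and a direction is given for a paired gene only where both scalings passed the threshold, or the exception is named.

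Of 37 gene lists fixed in advance, those with at least 3 tested features were tested with camera in limma 3.58.1, at its preset correlation of 0.01 and with an estimated correlation, and with fry. On the features' own identifiers 31 lists could be tested, and through paired features 7, among paired features alone and with the paired scaling. FKB2, 1 of the list symbols, was not found. Counts of list members are given over all features and adjusted over the list alone.

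Named genes followed a rule: ATG1, ATG8, ATG9, ATG14, GAP1, MEP2, TRK1 and PHO84 in each comparison, the 4 largest rises and 4 largest falls among called features with a gene symbol, a mean of at least 10 CPM and the same direction in both batches, the 2 leading members of autophagy_core and of called lists, and the 4 deleted markers. For paired genes the added rule took the 8 largest rises and 8 largest falls among those called in both scalings under the same conditions and with whole reads in each library, and every list member with a paired feature. Features with reads divided between copies by the quantifier are marked uncertain. Where a group held 0 reads, a fold given as at least a value counts that group at a floor of 3 reads per library. These bounds and the counting intervals use TMM sizes. The paired scaling gave nitrogen libraries 1 and 2 effective sizes of 186902 and 175520, against 753657 and 721199 with TMM. This cut was larger than in the other libraries, so bounds and intervals for falls in nitrogen starvation are smaller with it.

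The replicate number equals the batch number in the labels, so the numbers pair the samples. Deviations of same-numbered libraries from their group means correlated across features at -0.02 (control with nitrogen), -0.02 (control with potassium) and 0.06 (nitrogen with potassium). A fit with the replicate block was run as an alternative and left 2 residual degrees of freedom. No libraries were duplicates: the chi-square per degree of freedom between the 2 libraries of a group was 5.59 for control, 6.27 for nitrogen and 20.1 for potassium.

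The edgeR step was tested on simulated counts for the real features, with known changes, in 1 seeded set per comparison. It recovered 13.4%, 37.3% and 78.8% of features changed 2-, 4- and 8-fold in the simulation of nitrogen against control, on 1772 features in the fit. The percentages were 13.4%, 56.7% and 74.2% for potassium against control, on 1709 features, and 8.96%, 74.6% and 86.4% for nitrogen against potassium, on 1678 features. False calls numbered 2, 4 and 3 in the same order, and 0 recovered features had the wrong direction. Apart from the simulated list, a small part of the features changed in these sets, with directions drawn at random. The simulation therefore did not test calls or directions where most features move the same way, as in nitrogen starvation with the paired scaling. The simulated list was found in each comparison, with 1, 0 and 1 other lists called.

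Alternatives comprised DESeq2 1.42.0, RLE factors, library size alone, TMM without ribosomal genes, other filters, the block, fits of 2 groups, glmTreat at a log2 fold change of 1, limma-trend on log2(value + 1) of the deposited normalised counts and of TPM, and leaving out each library. Added after the data had been seen were the paired scaling, leaving out features opposite ribosomal RNA, the reads recovered from the deposited table, a 90% overlap and whole reads for pairs. Shares of reads carry 95% Wilson intervals, which cover counting error only, since the reads have no molecular identifiers. Figures and intervals used Python 3.11.15, matplotlib 3.10.9, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.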

Results

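RNA was measured in 6 yeast libraries, 2 from untreated cells, 2 from cells starved of nitrogen for 1 h and 2 from cells starved of potassium for 1 h. The series concerns autophagy, the delivery of cytoplasm to the vacuole for breakdown, under potassium starvation. The 2 control libraries held 425919 and 418010 reads, the 2 nitrogen libraries 357839 and 374245, and the 2 potassium libraries 359355 and 402342. Features opposite the ribosomal RNA genes took 22.2% (95% Wilson interval 22.1 to 22.3) and 28.2% (28.0 to 28.3) of reads in the control libraries. The shares were 19.4% (19.2 to 19.5) and 26.3% (26.2 to 26.5) in the nitrogen libraries, and 26.4% (26.2 to 26.5) and 44.7% (44.5 to 44.8) in the potassium libraries. Potassium library 2 had the fewest reads left for other features. The chi-square per degree of freedom between the 2 libraries of a group was 20.1 for potassium, against 5.59 for control and 6.27 for nitrogen.

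Several of the most abundant features lay opposite genes. The feature opposite CDC19, pyruvate kinase, held a mean of 25130 reads per library, the feature opposite GPM1, phosphoglycerate mutase, 20805, and the feature opposite PGK1, phosphoglycerate kinase, 9559. The identifiers CDC19, GPM1 and PGK1 themselves held 10.3, 9.5 and 12.2 reads. Among 379 pairs of a gene and the feature opposite it with a mean of at least 20 reads on both together, the feature exceeded the gene per base in 355, with a median log2 ratio of 6.76 (quartiles 5.11 and 8.24). Paired features took 61.4% and 56.7% of reads in the control libraries, 28.5% and 26.2% in the nitrogen libraries, and 50.7% and 41.9% in the potassium libraries. In the comparisons below, the name of a gene with a paired feature stands for the reads under that opposite feature, and genes read under their own identifier are named as such. Own identifiers name the strand that held far fewer reads in most pairs, so values under them are read counts on that strand and are not taken as levels of the genes' messages.

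**Figure D1:**
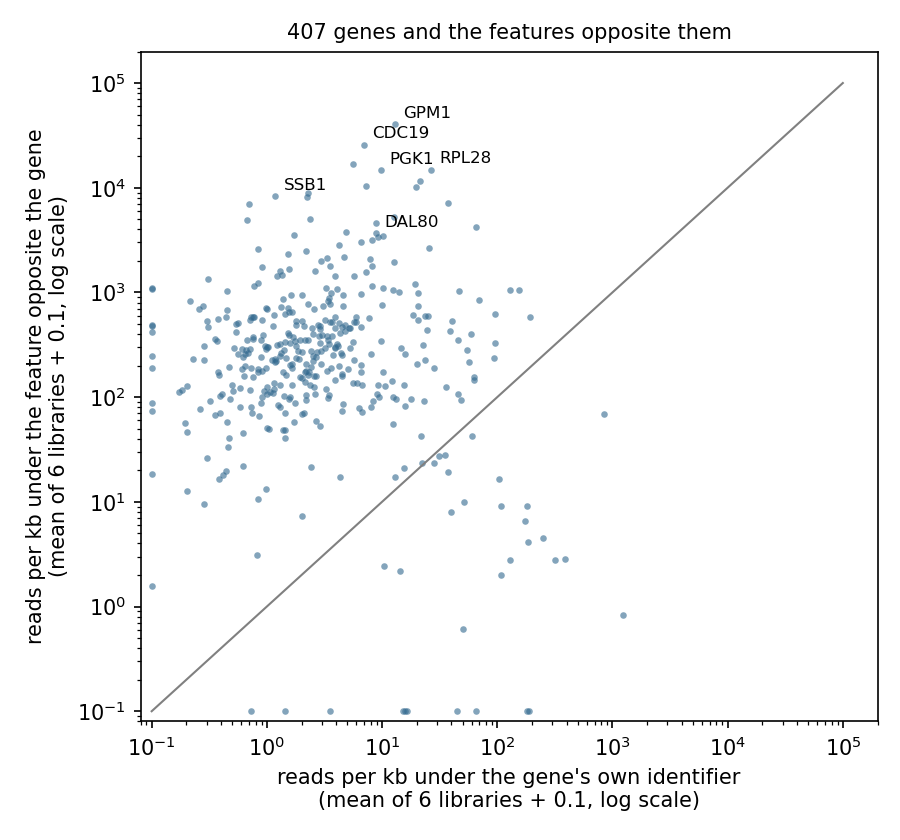
Reads per kb under the identifier of a gene (horizontal, log scale) and under the feature opposite it (vertical, log scale), means of 6 libraries plus 0.1, for 407 pairs; the grey line marks equal values. Most points lie above the line, and the 6 labelled genes carry far more reads opposite them than on their own identifier.

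Nitrogen starvation was compared with no treatment to see which transcripts change when the nitrogen source is withdrawn for 1 h. DAL80, a GATA factor that represses genes for the use of poor nitrogen sources, rose from 11.1 ± 3.95 to 6423 ± 27.3 CPM (SD, n = 2 each), a log2 fold change of 9.11 (SE 0.44, adjusted p = 7.9e-06). DAL7, malate synthase of allantoin breakdown, rose 41.6-fold from 137 ± 4.01 to 5695 ± 234 CPM (log2 5.38, SE 0.30, adjusted p = 1.0e-05). GAT1, an activator of the same gene set, rose 6.59-fold (log2 2.72, SE 0.29, adjusted p = 1.4e-04). MET28 and MET2, both of sulfur and methionine metabolism, rose 21.9- and 12.2-fold, and ARG5,6, an enzyme of arginine synthesis, rose 11.9-fold. HVG1, a putative nucleotide sugar transporter, rose 7.17-fold and RNP1, an RNA-binding protein, 6.33-fold. Ribosomal protein genes fell: RPL28 went from 53350 ± 1612 to 849 ± 308 CPM (log2 -5.97, SE 0.50, adjusted p = 5.4e-05), and SSB1, a chaperone bound to ribosomes, from 44270 ± 678 to 559 ± 124 CPM (log2 -6.31, SE 0.52, adjusted p = 4.9e-05). NOP13, NSR1 and NOP56, all nucleolar proteins, fell 75.7-, 70.6- and 65.4-fold, and RPL22A and RPL8B 73.8- and 63.3-fold.

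The DAL80 reads lay under YKR033C, an open reading frame on the minus strand of chromosome XI at 506879 to 507304 (R64), 407 bases of which lie opposite the single exon of DAL80 at 506898 to 507707. Its reads numbered 4 and 2 in the control libraries, 4826 and 4646 in the nitrogen libraries, and 4 and 7 in the potassium libraries. The DAL7 reads lay under YIR030W-A on the plus strand of chromosome IX at 412899 to 413282, 268 bases opposite DAL7. The RPL28 reads lay under YGL102C on the minus strand of chromosome VII at 311505 to 311933, 423 bases opposite RPL28.

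**Figure D2:**
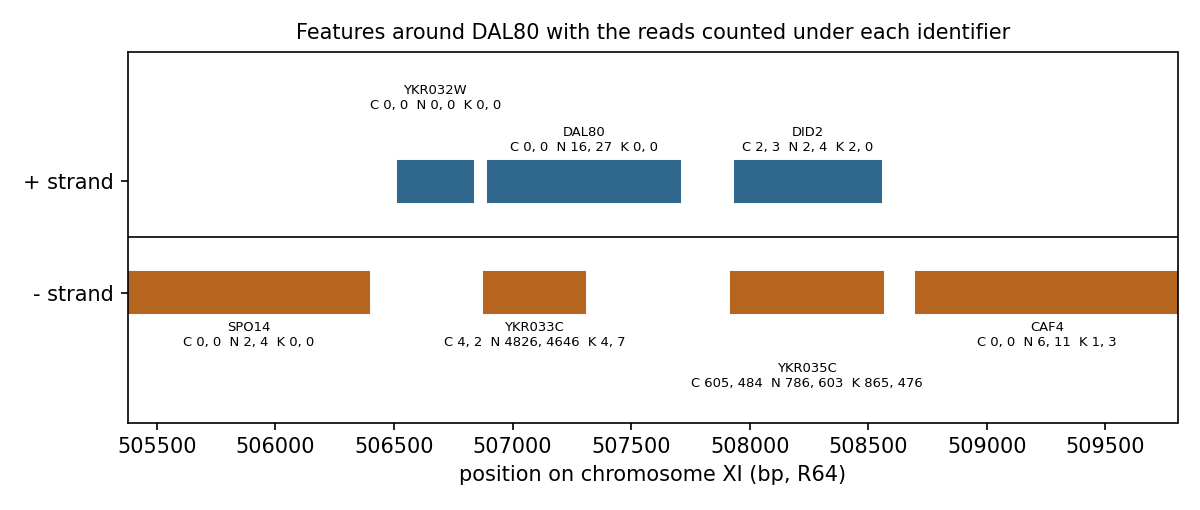
Map of the features around DAL80 on chromosome XI, plus strand above and minus strand below the line, with the reads counted under each identifier in the 2 control (C), 2 nitrogen (N) and 2 potassium (K) libraries. YKR033C, opposite DAL80, holds 4826 and 4646 reads in nitrogen starvation, and DAL80 itself 16 and 27.

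By list, all 16 ribosomal protein genes read through a paired feature fell in nitrogen starvation under both scalings, and also adjusted over the list alone; their median log2 fold change was -5.65, or -4.34 with the paired scaling. The change of RPL36A was the smallest (log2 -2.50) and lost its call with TPM and with library size alone (adjusted p = 0.18). The reads of RPL12A and RPL12B, near-identical copies, are uncertain. Of the ribosome assembly list, NOP4, NOP56, NSR1, RRP9 and RRP14 fell, 5 of 5, with NSR1, a nucleolar RNA-binding protein, at log2 -6.14 (SE 0.65, adjusted p = 1.4e-04). RPC19 and RPC53, subunits of RNA polymerases that make ribosomal and transfer RNA, fell by 3.26 and 3.48 on the log2 scale, 2 of 2. Of the glycolysis list, CDC19, PGK1 and GPM1 fell, 3 of 3: CDC19 went from 135100 ± 277 to 5795 ± 593 CPM (log2 -4.54, SE 0.62, adjusted p = 6.1e-04), and PGK1 and GPM1 had log2 fold changes of -4.71 and -4.05. The chaperones SSA1 and CPR6 fell, 2 of 2, with log2 -4.15 and -2.53, CPR6 without its call under library size alone or TPM. Of the nitrogen catabolite repression list, DAL80, DAL7 and GAT1 rose, and CAR2, ornithine transaminase, did not pass (log2 -1.09, SE 0.78, adjusted p = 0.28). Among 3 amino acid synthesis genes ARG5,6 rose under both scalings, TRP4 rose only with the paired scaling (log2 0.33 and 1.64), and LEU9 had log2 -0.91, or 0.40 with the paired scaling. GNP1, an amino acid permease, fell by 6.06 on the log2 scale, and HIP1, a histidine permease, had log2 -1.86, or -0.54 with the paired scaling.

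Other lists had few paired features. MET2 and MET28 were 2 of 2 sulfur genes that rose. Of 3 tRNA synthetase genes GLN4 fell (log2 -3.21), while ILS1 (-1.37) and MES1 (-1.43) had -0.05 and -0.12 with the paired scaling; camera gave an adjusted p of 0.41. IDH2, a citric acid cycle enzyme, CDC21 and CDC6, of DNA replication, fell by 2.66, 3.54 and 2.38 on the log2 scale; CDC6 lost its call with library size alone and with TPM, and IDH2 with TPM. CDC9, DSE3, HAC1, CNE1 and 2 features opposite CCC2 had log2 -1.39, -1.43, -0.92, -1.36, -1.23 and -1.14, none of them called as lower with the paired scaling. ATG16, of autophagosome formation, had log2 0.61 (adjusted p = 0.18), or 1.92 with the paired scaling (adjusted p = 0.0011), and CUE5, a receptor of selective autophagy, -0.10 or 1.21. AVT3, PMR1, ERG27, NHX1, ARN2, SPS19 and GPH1 had log2 -0.17, -0.59, -0.09, 0.70, 0.15, 0.79 and 0.54 and did not pass with TMM, but all 7 were called higher with the paired scaling, at 1.14, 0.73, 1.23, 2.01, 1.45, 2.08 and 1.84. PRM6 held 1 and 0 reads in the control and 0 and 0 in the nitrogen libraries.

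Camera, run among the paired features, called 4 of 7 lists in nitrogen starvation: nitrogen catabolite repression higher (adjusted p = 0.0017), and ribosomal proteins (1.4e-12), ribosome biogenesis (6.1e-04) and glycolysis (0.0017) lower. Every one of these calls was lost with an estimated correlation, each at adjusted p = 0.19. Fry, which does not compare a list with the other features, called these 4 lists (adjusted p from 7.4e-04 to 0.0020). It also called amino acid biosynthesis (7.4e-04) and tRNA synthetases (0.028), but not the iron regulon (0.18). Over all 2325 features 601 rose and 474 fell, and among the 365 paired features 21 rose and 217 fell. With the paired scaling 1333 features rose and 175 fell, among paired features 104 and 92, with library size alone 1458 and 115, and with TPM 1589 and 94. Among paired features 21 rose and 92 fell in both TMM and paired scaling. RNP1 lost its call without control library 1, control library 2 or nitrogen library 2 (adjusted p up to 0.088).

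Under their own identifiers, none of ATG1, ATG8 and ATG9, which encode the kinase, the ubiquitin-like protein and the membrane protein of autophagosome formation, held enough reads to be tested. ATG8 was at 0 in all 6 libraries, ATG1 held 2 and 4 reads in the control and 6 and 2 in the nitrogen libraries, and ATG9 held 1 and 5, and 4 and 8. ATG14 had a log2 fold change of 0.76 (SE 0.51, adjusted p = 0.25), MEP2, an ammonium permease, 0.12 (adjusted p = 0.90), and TRK1, the main potassium importer, -0.34 (adjusted p = 0.69). PHO84, a phosphate transporter, had 1.59 (SE 0.62, adjusted p = 0.063), and with the replicate block an adjusted p of 0.035. Reads under GAP1, the general amino acid permease, were 0 in both control libraries and 30 and 34 in the nitrogen libraries, at least 3.78-fold higher (adjusted p = 0.0033). Reads under the ATG2 identifier rose (log2 3.56, SE 0.61, adjusted p = 0.0019), and those under ATG18 rose (log2 2.25, adjusted p = 0.020), a call lost without control library 2 or nitrogen library 1 (adjusted p up to 0.10). Rises under own identifiers included those of DIM1 and POG1, at 0 in both control libraries and at least 27.5- and 7.48-fold higher, and of MKK2, with 102 and 101 reads in the nitrogen libraries against 0. DESeq2 did not call POG1. The largest falls with TMM included RPS31 and CUP1-1, at 0 in both nitrogen libraries and at least 22.6- and 16.8-fold lower. The others were DRS1, 115-fold lower (counting interval 19.5 to 4646, 1 read in nitrogen), and RPL36B, 78.4-fold lower (13.0 to 3207, 1 read), whose reads are shared with a copy. These bounds and intervals are smaller with the paired scaling. Of the deleted markers, LEU2, MET17 and URA3 were at 0 in each library and HIS3 held up to 7 reads. CDC19 and other abundant genes also held few reads under their own identifiers, so these markers were not used as a check of the strain. Of 5 autophagy_core identifiers tested, reads rose under 2, and under 2 adjusted over the list alone (camera adjusted p = 0.80); whether these are reads of the autophagy genes' messages was not shown. By camera 0 of 31 lists were called on own identifiers, with 0 at an unadjusted p under 0.05, while fry called 17.

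Potassium starvation was compared with no treatment to see which transcripts change when potassium is withdrawn. PRM6, on the fixed list of potassium and cation homeostasis, held 1 and 0 reads in the control and 144 and 33 in the potassium libraries. The ratio from the pooled reads per effective library size was 161 (counting interval 28.5 to 6389). The edgeR fit gave a log2 fold change of 7.01 (SE 0.94, adjusted p = 0.0061). GPH1, glycogen phosphorylase, rose 44.7-fold from 32.7 ± 6.88 to 1455 ± 871 CPM (n = 2 each; log2 5.48, SE 0.57, adjusted p = 0.0016). RGI1, a gene of respiratory growth, rose 34.8-fold, GCY1, a glycerol dehydrogenase, 13.4-fold, and ARO9, an aromatic aminotransferase, 5.49-fold. DIC1, the mitochondrial dicarboxylate carrier, fell from 1758 ± 218 to 189 ± 7.27 CPM (log2 -3.22, SE 0.28, adjusted p = 0.0013), and LEU9, an enzyme of leucine synthesis, fell 6.52-fold. REG2, a phosphatase regulator of glucose repression, rose 7.82-fold. ECM1, SAS10, REX4 and NOP13, all of ribosome assembly, fell by 2.64, 2.49, 2.36 and 2.16 on the log2 scale, and YIP3, of vesicle transport, by 2.10. NSR1 went from 12630 ± 1943 to 2303 ± 1305 CPM (log2 -2.46, SE 0.54, adjusted p = 0.027). ECM1, SAS10, REX4, NOP13, YIP3 and NSR1 lost their calls with TPM, and NOP13, YIP3 and NSR1 also with glmTreat.

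The PRM6 reads lay under YML047W-A on the plus strand of chromosome XIII at 179893 to 180258, 242 bases opposite PRM6, the GPH1 reads under YPR160C-A on the minus strand of chromosome XVI at 862577 to 862861, within GPH1, and the DIC1 reads under YLR349W on the plus strand of chromosome XII at 827521 to 828027.

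Among lists, MET2 and MET28 rose, 2 of 2 sulfur genes (log2 2.44 and 2.18). DAL7 rose 3.13-fold (log2 1.65, adjusted p = 0.010), 1 of 4 nitrogen catabolite repression genes over all features. Adjusted over the list alone 2 of the 4 rose, or 3 with the paired scaling. DAL80, GAT1 and CAR2 had log2 0.76, 0.58 and 2.08 and did not pass over all features. CAR2 had an adjusted p of 0.11, or 0.027 with the replicate block. DAL7 and MET28 lost their calls with TPM, and DAL7 also with glmTreat. Of the 16 ribosomal protein genes 11 fell, or 13 with the paired scaling and 16 adjusted over the list alone. The median log2 fold change of the 16 was -1.59. All 11 calls were lost with TPM and with glmTreat. RPL28 was among the 11 (log2 -1.73, adjusted p = 0.037) and did not pass with the replicate block (adjusted p = 0.051). Of 5 ribosome assembly genes 4 fell, or 5 adjusted over the list alone, and the 4 calls were lost with TPM and with glmTreat. RRP9 had log2 -1.29 (adjusted p = 0.074, or 0.010 with the block). RPC19 and RPC53 fell, 2 of 2, by 1.37 and 1.33 on the log2 scale, calls lost with library size alone, with TPM, and without control library 2 or potassium library 1. The 3 glycolysis genes did not pass, with CDC19 at log2 -0.06, GPM1 at 0.16 and PGK1 at 0.19, and SSA1 and CPR6 did not pass at 0.11 and -0.11. MES1 and GLN4 fell, 2 of 3 tRNA synthetase genes (log2 -1.06 and -1.22, camera adjusted p = 0.12), with ILS1 at -0.44. Both falls lost their calls with library size alone, TPM and glmTreat, and that of GLN4 also with limma on the deposited normalised counts and in the fit of 2 groups. CUE5 had log2 0.55 (adjusted p = 0.16), and with the paired scaling it was called higher (0.74, adjusted p = 0.048). ATG16 had log2 0.52 (adjusted p = 0.39), ARG5,6 0.44, TRP4 -0.46, GNP1 -0.92, NHX1 -0.02, PMR1 0.05, IDH2 -0.84 and ERG27 -0.21, and none of these passed. HIP1 and ARN2, at log2 -0.91 and -0.93, had adjusted p of 0.095 and 0.12, or 0.027 and 0.048 with the block. Camera among the paired features called 3 of 7 lists, nitrogen catabolite repression higher (adjusted p = 0.031) and ribosomal proteins (2.9e-09) and ribosome biogenesis (0.0027) lower. All 3 were lost with an estimated correlation, each at adjusted p = 0.40. Fry called these 3 lists (adjusted p from 0.024 to 0.029), amino acid biosynthesis (0.024) and tRNA synthetases (0.028). It did not call glycolysis (0.10) or the iron regulon (0.13).

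In total 110 features rose and 107 fell, among paired features 24 and 54, and with the paired scaling 133 and 84, or 30 and 50 among paired features; with library size alone 70 rose and 41 fell. The 217 calls became 92 without control library 1, 72 without control library 2 and 71 without potassium library 1, and the 78 paired calls became 34, 26 and 29. PRM6, GPH1, RGI1, GCY1, REG2, ARO9, MET2, MET28, DIC1, LEU9, ECM1, REX4 and NOP13 kept their calls in each of the 6 fits without 1 library. The other paired genes named lost theirs in at least 1: NSR1 without control library 2 or potassium library 1 (adjusted p up to 0.14), DAL7 without either control library (up to 0.092), and SPS19, of peroxisomal fatty acid breakdown, which rose 7.40-fold, without control library 1, control library 2 or potassium library 1 (up to 0.096). All 11 ribosomal protein calls were lost without control library 1 or potassium library 1. CDC21 had log2 -1.55 (adjusted p = 0.049, and 0.051 with the block).

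With the same limit on own identifiers, 5 autophagy_core genes could be tested and 0 were called (camera adjusted p = 0.93; ATG14 log2 -0.43, VPS34 1.01, ATG18 0.84; adjusted p = 0.72, 0.26 and 0.52). TRK1 had log2 0.19 (adjusted p = 0.91), PHO84 0.01 and MEP2 -0.77 (adjusted p = 0.62). GAP1, with 6 and 1 reads against 0 in both control libraries, did not pass (adjusted p = 0.10), and its fold cannot be stated. ATG8 was again at 0. The rises of ASP3-3, NPP1, ARP10 and MKK2, at 0 in both control libraries, were at least 15.5-, 3.96-, 1.81- and 1.26-fold, with ASP3-3 reads shared between copies. ASP3-3 kept its call in each of the 6 fits without 1 library, NPP1 lost it in 4 (adjusted p up to 0.097), ARP10 in 5 (up to 0.14) and MKK2 in all 6 (up to 0.16), and DESeq2 called none of these 4 genes. The falls of YLF2, SEC20 and WTM1 (log2 -3.63, -3.42 and -3.29) were lost without potassium library 1, and that of DBP1, 23.1-fold lower (3.72 to 956, 1 read in potassium), without 3 of the libraries. No list was called by camera, with 4 of 31 at an unadjusted p under 0.05, and fry called 2.

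Nitrogen and potassium starvation were compared directly, which tests whether their changes differ. DAL80 was 326-fold higher in nitrogen starvation (log2 8.35, SE 0.41, adjusted p = 9.2e-06), DAL7 13.3-fold (log2 3.73, SE 0.27) and ARG5,6 8.77-fold (log2 3.13, SE 0.34). GAT1, MET28 and YMC1, a mitochondrial carrier, were 4.42-, 4.85- and 4.34-fold higher, and MNC1 and DIA1 13.1- and 6.74-fold. PRM6 had 0 reads in both nitrogen libraries and was at least 68.0-fold lower there with TMM, a bound that is smaller with the paired scaling. CTR1, the high-affinity copper importer, was 48.6-fold lower (log2 -5.60, SE 0.57, adjusted p = 2.7e-04). RGI1 and GPH1 were 41.8- and 30.8-fold lower, PGK1 29.9-fold, GNP1 35.3-fold, SSB1 25.7-fold, RPL22A 22.4-fold, and CDC19 22.3-fold (log2 -4.48, SE 0.62, adjusted p = 7.4e-04).

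Of the fixed lists, 3 nitrogen catabolite repression genes were higher in nitrogen starvation and CAR2 was lower (log2 -3.17, SE 0.72, adjusted p = 0.0083), a call lost without potassium library 2 (adjusted p = 0.067) and with library size alone. All 16 ribosomal protein genes were lower, or 13 with the paired scaling, with a median log2 fold change of -4.03. RPL13B, RPS27A and RPL36A lost their calls with the paired scaling, library size alone and TPM, and RPL13B also with DESeq2. All 5 ribosome assembly genes and all 3 glycolysis genes were lower under both scalings, but RRP9 lost its call with library size alone and with TPM, and RRP14 with TPM. LEU9 and ARG5,6 were higher, with log2 1.79 and 3.13. MET2 was 2.25-fold higher (adjusted p = 0.020), a call lost without nitrogen library 2 or either potassium library (adjusted p up to 0.11). RPC19 and RPC53 were lower, 2 of 2, with log2 -1.89 and -2.16, and SSA1 and CPR6 with -4.26 and -2.43. RPC19 and RPC53 lost their calls with library size alone and with TPM, and CPR6 with TPM. Camera called 5 of 7 lists. Nitrogen catabolite repression and amino acid biosynthesis were higher (adjusted p = 0.0023 each). Ribosomal proteins (2.2e-10), ribosome biogenesis (0.0023) and glycolysis (6.5e-04) were lower. All 5 calls were lost with an estimated correlation (adjusted p from 0.20 to 0.26). Fry called these 5 lists (adjusted p from 5.1e-04 to 0.011) and the iron regulon (0.042), but not tRNA synthetases (0.64). Over all features 542 were higher and 450 lower, among paired features 20 and 209, and with the paired scaling 1149 and 176, or 76 and 88 among paired features. In both scalings 20 paired features were higher and 88 lower. With library size alone 1209 features were higher and 97 lower.

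Under own identifiers, GAP1 was 1.86 higher on the log2 scale (adjusted p = 0.042, and 0.065 with the block), a call lost without nitrogen library 1, nitrogen library 2 or potassium library 2 (adjusted p up to 0.16). Reads under ATG2 were higher (log2 2.68, adjusted p = 0.0049), ATG18 had log2 1.41 (adjusted p = 0.080, or 0.042 with the block), ATG14 1.18 (adjusted p = 0.10) and PHO84 1.58 (adjusted p = 0.066, or 0.044 with the block). MEP2 and TRK1 had log2 0.89 and -0.52 and did not pass. DIM1, CRT10, POG1 and MAL12 were at 0 in both potassium libraries and at least 29.0-, 19.0-, 7.90- and 7.30-fold higher in nitrogen starvation, MAL12 with shared reads and lost without potassium library 1. DESeq2 did not call POG1, MAL12, ASP3-3 or GAP1 in this comparison. ASP3-3, CUP1-1 and RPS31 were at 0 in both nitrogen libraries and at least 43.7-, 33.0- and 7.47-fold lower with TMM. These bounds are smaller with the paired scaling. SRO9 had log2 -5.88. By camera 0 of 31 lists were called, 0 at an unadjusted p under 0.05, and fry called 12.

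Both starvations were compared with the same 2 control libraries. Of the features called, 48 rose in both and 87 fell in both, against 28.4 and 21.8 for independent lists, and 12 moved in opposite directions. With the paired scaling 96 rose and 57 fell in both, against 76.3 and 6.32 for independent lists; 9 rose in nitrogen and fell in potassium starvation and 2 did the reverse, compared with 2 and 10 with TMM. Across features, which are not independent, the log2 fold changes correlated at 0.47, with a covariance of 1.64. In 50 simulations all libraries, controls included, were drawn anew from the control means, and 2 unchanged groups were compared with the same simulated controls. The mean correlation was 0.61 (0.54 to 0.67) and the mean covariance 0.51 (0.40 to 0.61), so the observed covariance was larger by 1.13. At most 1 feature in a simulated set was called in both in the same direction, against 135 observed. The simulated groups held no true change, so few calls of any kind were possible in them. The simulations therefore cannot tell shared changes from separate changes measured against the same noisy controls. With 2 controls, separate controls for each starvation would mean 1 control library each, and such a split was not run. Without control library 1, control library 2 or potassium library 1 the 135 shared calls became 50, 41 and 39. TMM and the paired scaling had BUR6 and CTR1 falling in nitrogen and rising in potassium starvation, with the fall of BUR6 lost under library size alone and TPM and its rise in each fit without 1 library.

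**Figure D3:**
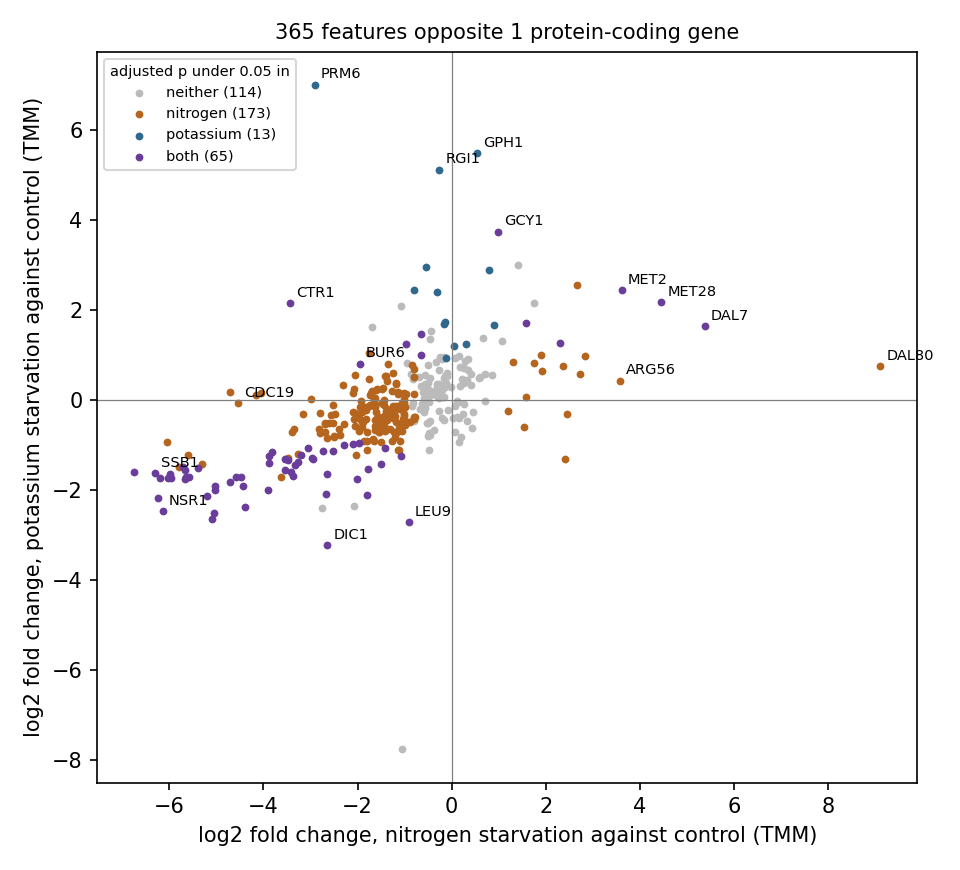
Log2 fold changes against control in nitrogen (horizontal) and potassium starvation (vertical) for 365 features opposite 1 protein-coding gene, TMM scaling, coloured by adjusted p under 0.05 in neither (114), nitrogen only (173), potassium only (13) or both (65). DAL80 lies far right near 0 on the vertical axis, PRM6, GPH1 and RGI1 lie at the top, and the ribosomal and assembly genes lie at the lower left.

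**Figure D4:**
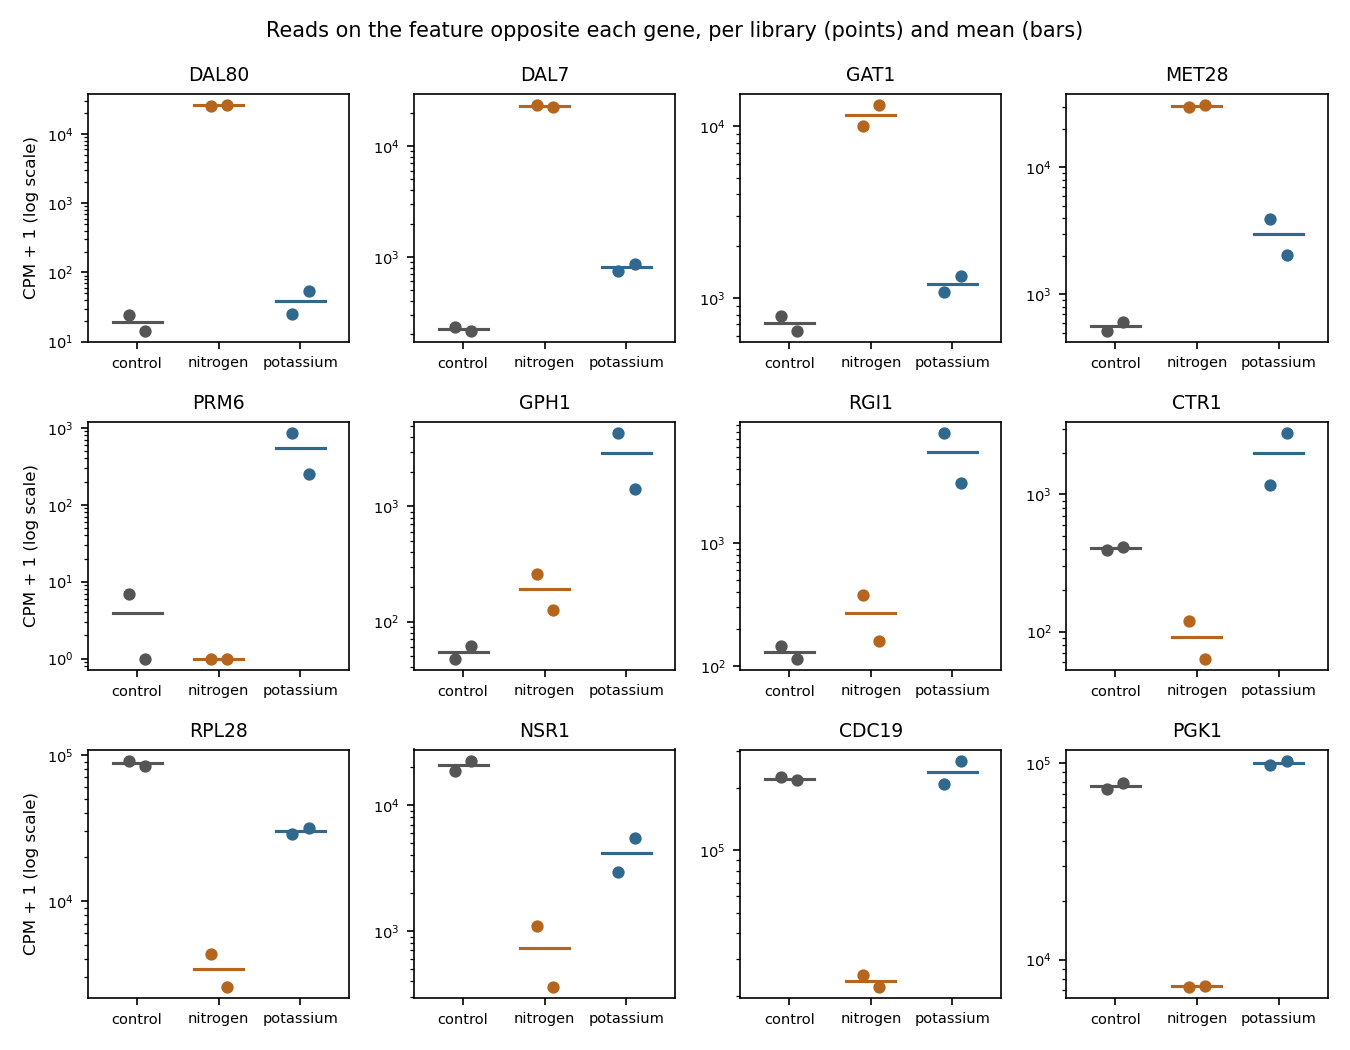
CPM plus 1 (log scale, libraries scaled over the paired features) under the feature opposite each of 12 genes, points per library and bars for means of 2. DAL80, DAL7, GAT1 and MET28 are highest in nitrogen starvation, PRM6, GPH1, RGI1 and CTR1 in potassium starvation, and RPL28, NSR1, CDC19 and PGK1 are lowest in nitrogen starvation.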

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

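The tests of strand setting, of counting without regard to strand, of leaking reads and of carry-over were chosen after the results had been seen. The others were planned, but the tests of shifted values, even background and low counts used the pairing. The pairing was chosen after the data had been seen, so these tests were not fixed before that. All of the tests address patterns that were found in the data.

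BUR6, a subunit of a transcription regulator, and CTR1, the copper importer, moved in opposite directions in the 2 starvations. CTR1 had log2 -3.45 (SE 0.57, adjusted p = 0.0016) in nitrogen and 2.16 (SE 0.48, adjusted p = 0.027) in potassium starvation, and the test of the difference gave -5.60 (SE 0.57, adjusted p = 2.7e-04), with 22 and 11 reads in the nitrogen against 196 and 375 in the potassium libraries. BUR6 had log2 -1.95 and 0.81 (adjusted p = 1.9e-04 and 0.045), and the difference was -2.77 (SE 0.22, adjusted p = 1.3e-04). Its fall in nitrogen starvation was lost with library size alone and with TPM, where it had log2 0.0792 (adjusted p = 0.85), while the difference kept its call in both. With the paired scaling the differences were -4.44 and -1.67. The potassium rise of CTR1 was lost without control library 1, control library 2 or potassium library 2 (adjusted p up to 0.099), and that of BUR6 in each of the 6 fits that left out 1 library (adjusted p from 0.062 to 0.26). No explanation was tested for either gene.

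The reads lie opposite the abundant genes. Counting without regard to strand would put as many reads per base on the gene, which was the case in 6.33% of the compared pairs, and a shift of values by 1 feature would put high counts beside glycolysis genes without a paired feature, where the median neighbour held 10.6 reads. A strand setting opposite to the library is a candidate explanation: the median log2 ratio of feature to gene was 6.76, after an earlier filter on the feature alone, which favours this outcome, had been replaced. It cannot be shown from these files, because the setting is not given in the sources used here. No biological explanation was tested.

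Unpaired features rose against the paired ones in nitrogen starvation. The unpaired set also holds features opposite a gene that did not meet the pairing rule. Leaking sense reads would make own identifiers follow their paired feature. The test took 34 genes whose paired feature fell in both scalings and whose own identifier held at least 30 reads. In these the own identifier differed by a median of 3.47 on the log2 scale (quartiles 1.55 and 4.60). Choosing genes by the fall and by own reads favours such a difference, so genes outside this set stay open. Even background such as genomic DNA would lift the lowest features too. Among unpaired features of at least 1 kb with no opposite-strand gene, the 10th percentile rose by 8.03% of the rise of the median. In reads per kb scaled to library size, it was 0 in control and 0.59 in nitrogen, against medians of 2.63 and 9.96. At this shallow depth a percentile so near the floor can stay low by counting error alone. The test therefore cannot exclude an even background. Low counts would remove the gap among features of at least 100 CPM, where it was 1.47. The gap was nearly the same with either scaling: the medians of unpaired and paired features were 0.58 and -1.18 with TMM and 1.88 and 0.14 with the paired scaling, so whether paired features fell or the others rose stays open.

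Potassium library 1 lay nearer to the nitrogen libraries than potassium library 2 (distances 2.04 and 2.31). Carry-over of nitrogen reads would bring DAL80 along with PRR2, yet above the control level DAL80 reached 0.0648% of the share that PRR2 reached. Subtracting the control level was not part of the stated test. A batch difference shared with the controls would give a positive correlation of the batch differences, which was -0.0233. The distances of potassium libraries 1 and 2 to the control libraries were 1.70 and 1.62. Their effective sizes with TMM were 353000 and 226314 reads, and whether this difference in depth moved the distances was not tested. The difference between the cultures themselves also stays open as untested.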

How the results depend on the processing

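The scaling over paired features, the pairs themselves and the recovered reads were chosen after seeing the data. Over 274 named gene comparisons and all alternatives, 4935 of 5461 values stayed on the same side of the threshold with no called value changing sign, 349 lost the call, 110 gained it and 67 changed sign with at least 1 of the compared values called. Among the 4935, 88 changed sign with neither value called, 22 for nitrogen against control, 40 for potassium against control and 26 for nitrogen against potassium. None of the 67 was in potassium starvation against control. The block changed the calls of PMR1 (nitrogen against control, adjusted p = 0.047, and nitrogen against potassium, 0.034) and CDC9 (nitrogen against potassium, 0.035), besides those given above, and no other call of a named gene.

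Counts moved by more than 1.5 times, or a list gained its call, as follows. With library size alone, potassium calls numbered 111, paired potassium calls 47, paired calls of nitrogen against potassium 136 and shared calls 82. With glmTreat, calls numbered 657 (153 paired) for nitrogen, 44 (17 paired) for potassium, 552 (132 paired) for nitrogen against potassium and 20 shared. With TPM, calls numbered 1683 for nitrogen, 22 (10 paired) for potassium, 149 paired for nitrogen against potassium and 13 shared. Pairs overlapping by 90% gave 108, 39 and 97 paired calls. Lists called were 2, 2 and 1 without a filter, 1 and 2 for nitrogen and potassium at 10 CPM in 2 libraries, 1 for potassium in the fit of 2 groups, 17, 2 and 12 with fry, and 4, 3 and 5 through paired features.

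DESeq2 called 880, 248 and 779 features, RLE factors 1072, 220 and 993, the block 1043, 231 and 967, and limma on the deposited normalised counts 1096, 231 and 964. Leaving out 1 library gave 755 to 1123, 71 to 231 and 664 to 979 calls, of which 201 to 256, 26 to 84 and 183 to 236 were paired, and 39 to 159 shared calls. Of the named calls 63 of 71, 14 of 49 and 61 of 72 stood in each of the 6 fits.

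The called sign changes for nitrogen against control were in genes that had fallen, or did not pass, with TMM. With library size alone, TPM and the paired scaling, in that order, CUE5 had log2 1.62, 1.92 and 1.21, AVT3 had log2 1.54, 1.83 and 1.14, LEU9 had log2 0.81, 1.12 and 0.40. In the same order, PMR1 had log2 1.16, 1.47 and 0.73, ERG27 had log2 1.65, 1.95 and 1.23, HAC1 had log2 0.81, 1.12 and 0.39. In the same order, CCC2 (first feature) had log2 0.49, 0.77 and 0.0716, CCC2 (second feature) had log2 0.59, 0.89 and 0.17. With TPM, HIP1 had log2 0.17, BUR6 had log2 0.0792. With library size alone and TPM, ILS1 had log2 0.38 and 0.67, MES1 had log2 0.30 and 0.60, CDC9 had log2 0.33 and 0.58. In the same order, DSE3 had log2 0.30 and 0.59, CNE1 had log2 0.37 and 0.68.

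The called sign changes for nitrogen against potassium follow. With library size alone, TPM and the paired scaling, in that order, CUE5 had log2 0.81, 1.10 and 0.47, AVT3 had log2 0.99, 1.26 and 0.64, HIP1 had log2 0.56, 0.82 and 0.19. In the same order, ILS1 had log2 0.56, 0.84 and 0.20, MES1 had log2 1.09, 1.37 and 0.74, CNE1 had log2 0.43, 0.70 and 0.0774. In the same order, HAC1 had log2 0.97, 1.31 and 0.66, CCC2 had log2 1.37, 1.69 and 1.05, IME4 had log2 1.41, 1.72 and 1.09. With TPM, RPL36A had log2 0.0292, CDC6 had log2 0.13. With library size alone and TPM, PMR1 had log2 0.81 and 1.11.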

Other observations

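The test of divergent promoters was chosen only after the result had been seen. For convergent neighbours the prediction was written before the test, but on features sorted by the pairing, which was chosen after the data had been seen. Features below were singled out after their values were seen.

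Some genes carried many reads under their own identifier, on the strand opposite their annotated one if the strand setting is reversed. PRR2, a protein kinase on chromosome IV at 74446 to 76545, rose from 55.7 ± 9.82 to 10350 ± 1414 CPM in nitrogen starvation (log2 7.54, SE 0.46, adjusted p = 1.8e-05, n = 2 each) and rose in potassium starvation by 2.83 on the log2 scale (adjusted p = 0.0066, and 0.054 without control library 1). DGR2, PAN6, SNX41 and COS111 rose by 6.21, 6.04, 5.79 and 4.97 on the log2 scale in nitrogen starvation; SNX41 has a paired feature with a mean of 222 reads, against 362 on its own identifier, and the other 4 genes have none. Downstream of PRR2 lies GDH2, a gene of glutamate breakdown, 528 bases away on the same strand, and downstream of PAN6 lies ATG32, a receptor of mitochondrial autophagy, 581 bases away. DGR2 and SNX41 also have a downstream neighbour on the same strand, OAC1 and RPN9, while that of COS111 is LDH1, convergent and 312 bases away. TAR1, on chromosome XII within the ribosomal DNA and opposite its RNA, held 17.4% to 40.5% of the reads of a library. IME4, a meiosis gene with the antisense transcript RME2, held more reads under its own identifier than RME2, unlike most pairs. The IME4 reads numbered 351, 288, 982, 1010, 471 and 314 in the 2 control, 2 nitrogen and 2 potassium libraries, and RME2 held a mean of 6. If the strand setting is reversed, the reads under IME4 lie on the strand of RME2, so this pair does not speak against a reversed setting.

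Transcripts of convergent neighbours that run past their ends would give such reads, and they would then be denser on features with a convergent downstream neighbour within 500 bases. They were not denser there. The median reads per kb was 2.058 for the 2554 convergent features (quartiles 0.80 and 5.97). It was 2.675 for the 1792 tandem features (quartiles 0.94 and 8.93), a ratio of 0.77. Tandem features may hold reads from another source, taken up next, so the ratio cannot exclude reads from convergent neighbours. Single features with a convergent neighbour, such as COS111, also stay open. Divergent transcription from the promoter of a downstream gene is a candidate explanation for the tandem features. The set tested was features whose tandem downstream neighbour within 500 bases belongs to the nitrogen repression or autophagy lists. Of these, 8 of 11 rose in nitrogen starvation and 0 fell. Their median log2 change exceeded that of the 584 other tandem features by 2.32 (3.37 against 1.05, permutation test with 100000 resamples, 2-sided, p = 0.0018). The features singled out above were left out, but PRR2 (528 bases) and PAN6 (581 bases) lay beyond that distance in any case. UTP10, upstream of GZF3, had log2 5.53 and HMS2, upstream of BAT2, 3.46. DAL7 and DAL3, both in this set, lie in a strongly induced cluster and may hold leaked reads. DAL4 (log2 -0.79), also in the set, belongs to the same cluster, and the permutation test treats these features as independent.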
